A study of Mus musculus with 6 samples.

How the data were processed

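In all, 6 libraries were analysed: 3 from CreER-positive mice with a floxed Scn9a gene and 3 from CreER-negative littermates, all female, grouped by the genotype label. Per the labels, lumbar ganglia L4 to L6 of both sides (6 ganglia) of 1 mouse made up each replicate, total RNA was purified with a lipid-tissue kit, and an Illumina instrument was used. Per the submitters' processing notes, reads were aligned with GSNAP to the mouse genome GRCm38 (mm10), with no version given. The counting tool, annotation release and strand setting are not given in the sources used here.

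Per the file headers, the authors' table for each library holds 36528 NCBI gene identifiers with a raw count, a gene width and an RPKM value. The deposited count is a whole number, and its sum ranges from 40237131 to 63332040 between libraries. The deposited RPKM equals the count divided by the width and by a library total. The sum of the counts lies 1.46% to 2.17% above that total. Some reads therefore appear to be counted for more than 1 gene. RPKM was not used in any test. For 77.7% of genes the width lies within 5% of the gene's full span in GRCm38.p6, so counts appear to include introns. Because no strand setting is known, reads of a gene and of an overlapping partner cannot be assigned to 1 of them.

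Identifiers were matched to symbols and positions of the GRCm38.p6 annotation: 31049 matched, and the 5479 without a symbol held 1.91% of counts. Genes were filtered with the defaults of filterByExpr (edgeR 4.0.16), which left 22043, and libraries were scaled with TMM factors. The test was edgeR's quasi-likelihood test of the group (R 4.3.3) with Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The common biological coefficient of variation was 8.99%. Nothing in the labels pairs the animals or gives a batch. CPM are TMM-scaled. Pairs of libraries of a group differed by more than sampling noise (chi-square per degree of freedom 5.64 to 40.7), so no pair looked like copies of 1 library.

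Before the data were examined, 14 pathway lists and 15 cell-type marker lists were fixed, together with the neighbours of Scn9a within 2 Mb. Lists were tested with camera (limma 3.58.1, correlation 0.01), camera with an estimated correlation, and fry, directional and mixed (changes in either direction), each with Benjamini-Hochberg adjustment over the 29 lists. List values in brackets are camera adjusted p values at the preset correlation unless another test is named, and gene values in brackets are log2 fold changes or, after leaving out a library, edgeR adjusted p values. Genes named in the text followed a rule also fixed in advance: Scn9a; the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 1 CPM and no overlap between groups; the opioid genes Penk, Oprm1, Oprd1 and Oprk1 and the sodium channel genes Scn1a, Scn3a, Scn7a, Scn8a, Scn10a and Scn11a; and in each list described the 2 to 4 genes with the smallest unadjusted p. Outside this rule, Jun, Zfp521, Piezo2, P2rx3, Lpar3, Cdk8 and Lars2 were chosen after their values were seen. Some genes that the rule takes are not reported here, and in their lists the next gene by p was named where needed. Scn9a was also tested by exact permutation on CPM.

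Alternatives fixed in advance were DESeq2 size factors, upper-quartile factors, total counts alone, no count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, robust and legacy quasi-likelihood settings, a test against a fold of 1.2, 1 surrogate variable (sva 3.50.0), a window of 1 Mb around Scn9a, and leaving out each library. Leaving out control replicate 2 and CreER-positive replicate 3 together, and leaving out 18 genes with excess reads, were added after seeing the data. On counts simulated for 22043 genes in 3 and 3 libraries, with 200 genes changed, the edgeR step recovered 69% of genes changed by a fold of 1.5 and 94% of those changed by a fold of 2, and 17 of the 194 calls (8.76%) were unchanged genes. Camera called a list shifted by a fold of 1.3 and 0 of 28 other lists. Genes were simulated independently of each other, so this does not test camera where the genes of a list move together. Figures were drawn with matplotlib 3.10.9.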

Results

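RNA of lumbar dorsal root ganglia was sequenced from adult female mice homozygous for a floxed Scn9a gene, which encodes the voltage-gated sodium channel Nav1.7 of sensory neurons. The mice either carried CreER, a tamoxifen-inducible Cre recombinase (pCAAG.Cre.ER in the labels), or were littermates without it (control, n = 3). CreER-positive mice formed the knockout group (n = 3). Each library came from the 6 pooled ganglia of 1 mouse, so the spread between libraries includes that between animals. Total counts were 40237131, 54677143 and 63332040 in control replicates 1 to 3. They were 61291709, 62625441 and 52309273 in CreER-positive replicates 1 to 3. Of 36528 listed genes, 27589 to 28328 per library had at least 1 count. The comparison asks which transcripts of the ganglia differ between floxed mice with and without CreER. The genotype label gives floxed Scn9a with CreER present or absent, and the deletion itself was not measured here.

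Scn9a itself (NCBI gene 20274, chromosome 2, 66480080 to 66635114 in GRCm38) had 635, 611 and 557 CPM (counts scaled by library size) in the controls and 620, 565 and 574 CPM in the CreER-positive libraries. The group means were 601 ± 39.9 and 586 ± 29.6 CPM (SD, n = 3). The log2 fold change was -0.04, with a 95% interval from -0.21 to 0.14. The difference was smaller than the spread between animals, with an edgeR adjusted p of 0.918 and an exact two-sided permutation p of 0.8; 3 animals against 3 allow no p below 0.1. The counts cover whole gene bodies for most genes, and the floxed exons are not given in the sources used here. Reads outside the deleted part are therefore counted, and this gene-level value does not check the group labels. The estimate was 0.00 without control replicate 1, the single alternative in which it was not negative.

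Of the neighbours of Scn9a within 2 Mb on chromosome 2, 16 genes were tested, among them the sodium channel genes Scn1a, Scn2a, Scn3a and Scn7a. None was called by edgeR over all genes, and 0 were called adjusted over the list alone. At an unadjusted p under 0.05 there were 3, Gm35265 (0.36), Grb14 (0.20) and Galnt3 (0.21), and DESeq2 and limma-voom called 0. Over all 22043 tested genes, 2330 had an unadjusted edgeR p under 0.05. The median log2 fold change was -0.04, the mean was 0.00, and the camera test had the direction up with a p of 0.866.

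Among called genes with a mean of at least 1 CPM, the largest rises were those of Dpyd, Esr1 and Penk. Dpyd (chromosome 3, 118562109 to 119432924), which encodes the first enzyme of pyrimidine breakdown, rose from 30.5 ± 1.24 to 132 ± 25.8 CPM (SD, n = 3). Its log2 fold change was 2.11 ± 0.13 (SE). Esr1 (chromosome 10, 4611989 to 5005633), oestrogen receptor alpha, rose from 23.7 ± 3.32 to 69.8 ± 11.8 CPM, a log2 fold change of 1.56 ± 0.13. The CreER protein contains an oestrogen receptor domain, and gene-level counts do not separate reads of the transgene from those of Esr1. Penk (chromosome 4, 4133536 to 4138815), which encodes the precursor of the enkephalin opioid peptides, rose from 4.67 ± 0.288 to 13.4 ± 4.44 CPM (1.52 ± 0.20). It had 9.84, 12.0 and 18.4 CPM in the CreER-positive mice and at most 4.94 CPM in a control. The lowest of these called genes, apart from predicted genes, were Wfdc2, a secreted WAP-domain protein gene (-2.14), Smyd1, a muscle histone methyltransferase gene (-1.77), and Ceacam10, an adhesion molecule gene (-1.74).

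By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 160 of 22043 tested genes changed between the groups, 36 higher and 124 lower in the CreER-positive mice. The CPM of the groups did not overlap for any of the 160, against 15.9% of tested genes and a chance share of 10%. The edgeR adjusted p was 0.000353 for Dpyd, 0.00141 for Esr1, 0.00951 for Penk and 0.00224 for Wfdc2. The other named rises were A630023A22Rik (1.15), the cation channel gene Trpc5 (1.10), Alkal2, a ligand gene of the receptor kinase ALK (1.03), Gpr119 (1.02), Serpina10 (0.84), the syndecan gene Sdc1 (0.83) and Tagln2 (0.79). The other named falls were Gm36090 (-1.88), Gm14317 (-1.80), Lrrc31 (-1.63), Cfap58 (-1.61), 4932435O22Rik (-1.61), C1ql4 (-1.59) and the zinc finger gene Bnc1 (-1.58). Of the 160 genes, 38 (23.75%) overlap another gene, against 35.2% of all tested genes. Among the 38 are 4932435O22Rik, Alkal2, Trpc5 and A630023A22Rik, and reads there cannot be assigned to 1 gene.

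Of the 20 genes named by size of change, 12 kept their call without any 1 library. Penk lost it without control replicate 2 (0.0741) or 3 (0.0669), against adjusted p values from 1.94e-13 (DESeq2) to 0.0741 over its 19 alternatives. Leaving out control replicate 1, 2 or 3 ended the calls of A630023A22Rik (0.184, 0.233 and 0.122), Trpc5 (0.0715, 0.0672 and 0.152), Serpina10 (0.176, 0.218 and 0.147) and Gpr119 (0.0697, 0.0575 and 0.0825). Cfap58 lost its call without control replicate 1 (0.0581) or 3 (0.0722), and Sdc1 (0.0590) and Tagln2 (0.0543) without control replicate 2. Without CreER-positive replicate 1 the calls of Trpc5 (0.0956) and Serpina10 (0.117) ended, and without replicate 2 those of Trpc5 (0.0861), Serpina10 (0.0766) and A630023A22Rik (0.126). The count of 160 became 71, 60 or 73 without control replicate 1, 2 or 3. It was 139 without CreER-positive replicate 1, 143 without replicate 2 (67 higher, 76 lower) and 568 without replicate 3 (333 higher, 235 lower). Without control replicate 2 and CreER-positive replicate 3, which stood apart in transcripts of non-neuronal cells, 108 genes were called (35 higher, 73 lower), 81 of them among the 160.

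**Figure D1:**
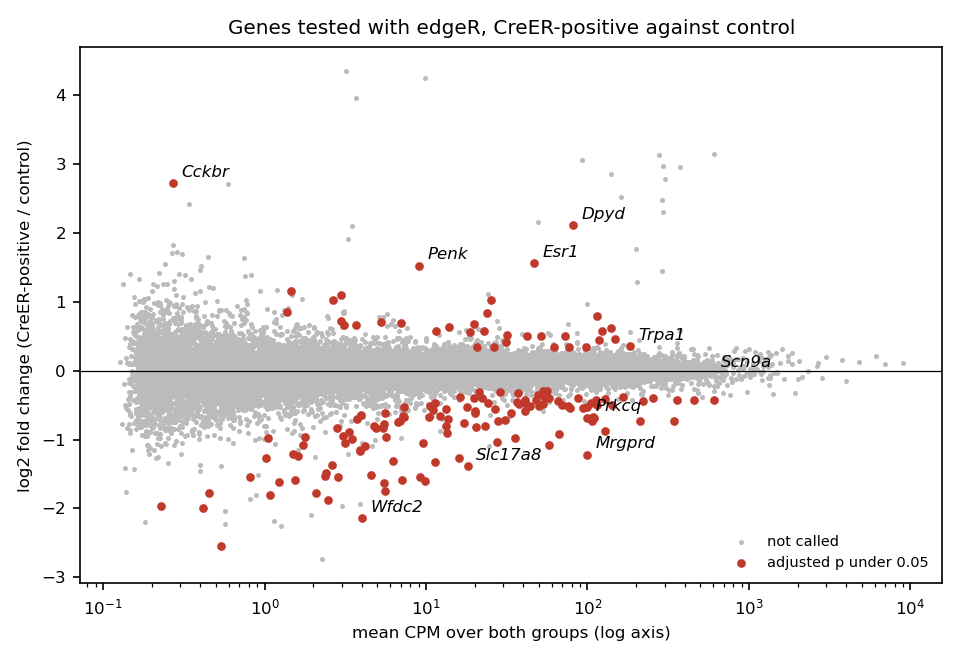
Log2 fold change (CreER-positive over control, vertical axis) against mean CPM (horizontal log axis) for the 22043 genes tested with edgeR, with the 160 genes at an adjusted p under 0.05 in red. Dpyd (2.11) and Esr1 (1.56) are the highest called genes above 10 CPM, and grey points above them at high CPM, such as Cdk8 (3.14), are genes with excess reads in CreER-positive replicates 1 and 3.

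Several markers of C-fibre low-threshold mechanoreceptors, unmyelinated touch neurons, and of non-peptidergic nociceptors were lower in CreER-positive ganglia. Of 6 tested mechanoreceptor markers, 4 fell. Slc17a8, the vesicular glutamate transporter VGLUT3, fell from 26.3 ± 1.55 to 10.1 ± 2.40 CPM (-1.38). Th, tyrosine hydroxylase, fell from 117 to 81.1 CPM (-0.53), and the transcription factor gene Pou4f2 (-0.75) and the secreted-protein gene Tafa4 (-0.50) fell as well. Zfp521 (-0.29) and the mechanically gated channel gene Piezo2 (0.06) did not pass. Of 19 non-peptidergic nociceptor and pruriceptor markers, 3 fell. Mrgprd (chromosome 7, 145314835 to 145324059), a receptor gene of non-peptidergic nociceptors, fell from 139 ± 4.69 to 59.8 ± 4.65 CPM (-1.22 ± 0.07). Prkcq, protein kinase C theta, fell from 122 to 76.2 CPM (-0.68), and Plxnc1, a semaphorin receptor gene, had -0.43. Mrgpra3 (0.29), P2rx3 (0.08) and Lpar3 (-0.04) were not called by edgeR, and DESeq2 called Mrgpra3 higher (0.0248).

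The mechanoreceptor list had a median log2 fold change of -0.52 and a camera adjusted p of 8.04e-19 over 29 lists, and the non-peptidergic list had -0.16 and 1.52e-10. With an estimated correlation between genes neither list was called (0.154 and 0.168), nor by fry's test for a shared direction (0.0632 and 0.0709). Fry's mixed test, for changes in either direction, called both (0.00612 and 9.70e-05). Adjusted over the list alone, 5 mechanoreceptor genes were lower, and 4 non-peptidergic genes were lower and 1 higher. The edgeR adjusted p was 0.000249 for Mrgprd, 0.000653 for Prkcq, 0.00337 for Slc17a8 and 0.00494 for Pou4f2, and these 4 calls held without any 1 library. Th (0.0183) lost its call without control replicate 2 (0.121) or 3 (0.116) or CreER-positive replicate 2 (0.0533). Tafa4 (0.0275) lost it without control replicate 1, 2 or 3 (0.132, 0.0855 and 0.108) or CreER-positive replicate 2 (0.0797). Plxnc1 (0.0437) lost it without control replicate 1, 2 or 3 (0.235, 0.212 and 0.165) or CreER-positive replicate 1 or 2 (0.0511 and 0.112), and Zfp521 passed without CreER-positive replicate 1 (0.04998). The mean of the mechanoreceptor markers against the control mean was -0.40, -0.56 and -0.76 on the log2 scale in CreER-positive replicates 1, 2 and 3. Replicate 3 also had the lowest mean of pan-neuronal markers (-0.15, against -0.02 to 0.05 in the other libraries).

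**Figure D2:**
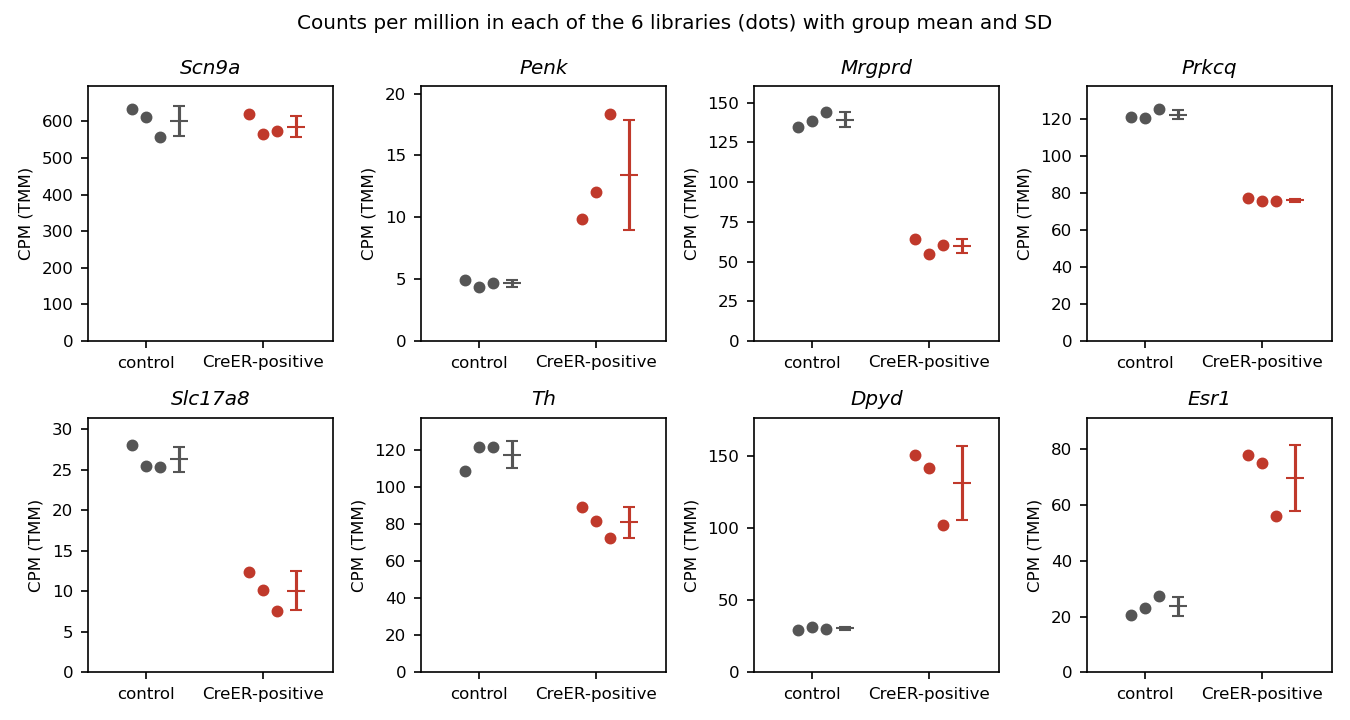
CPM (vertical axes, from 0) of 8 genes in each library, with control dots in grey and CreER-positive dots in red and with the group mean and SD (n = 3) beside them. Scn9a overlaps between groups, Mrgprd, Prkcq, Slc17a8 and Th are lower and Penk, Dpyd and Esr1 higher in all 3 CreER-positive mice.

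Lists of other neuron types were not called by camera. Of 11 peptidergic nociceptor markers, the substance P precursor gene Tac1 had 0.39 (edgeR adjusted p 0.0651) and the CGRP gene Calca 0.25 (0.431). The list had a median of 0.04 and a camera adjusted p of 0.145, with a call by fry's mixed test (0.000887), 1 gene higher adjusted over the list alone and 0 over all genes by edgeR, where 4 had an unadjusted p under 0.05. DESeq2 called 1, Tac1 (4.74e-05). Large-diameter A-fibre neuron markers had a median of 0.05 (0.616; Cadps2 -0.23, Necab2 -0.24), with 0 genes called by edgeR either way, 3 at an unadjusted p under 0.05 and 0 called by DESeq2. Pan-neuronal markers had a median of -0.02 (0.563), and the transcription factor gene Isl2 (-0.42) was lower adjusted over the list alone and by DESeq2 (9.92e-05), while Tubb3 (0.31) was not called by edgeR or DESeq2. Without CreER-positive replicate 3, Tac1 (0.0311), Isl2 (0.0150) and Tubb3 (0.0327) passed and the A-fibre list was called higher (0.0483). The peptidergic list was called higher without CreER-positive replicate 2 (0.0245).

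Genes that rise in sensory neurons after nerve injury were higher as a list in CreER-positive ganglia. Of 20 tested, 18 had a positive estimate. A single gene passed over all genes by edgeR, the cholecystokinin receptor gene Cckbr (2.71 ± 0.43, edgeR adjusted p 0.0266), on low counts of 2, 5 and 4 against 19, 27 and 35. The transcription factor genes Atf3 (0.64) and Sox11 (0.48) and the activin antagonist gene Fst (0.85) had edgeR adjusted p values of 0.0523, 0.0567 and 0.0539, and Jun had 0.54 (0.127). DESeq2 called 4, Atf3 (0.000485), Fst (0.000747), Sox11 (0.000611) and Jun (0.00105), and gave no adjusted p for Cckbr. Adjusted over the list alone, 9 genes were higher. The list's median was 0.21 and its camera adjusted p 4.11e-11, and the call held with an estimated correlation (0.0461) and by directional fry (0.0161). Cckbr lost its call without control replicate 1, 2 or 3 (0.132, 0.111 and 0.148) or CreER-positive replicate 2 (0.0552). Fst (0.0131) and Sox11 (0.0144) passed without CreER-positive replicate 1, and Atf3 (0.0154), Fst (0.0468) and Sox11 (0.0406) without replicate 3.

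**Figure D3:**
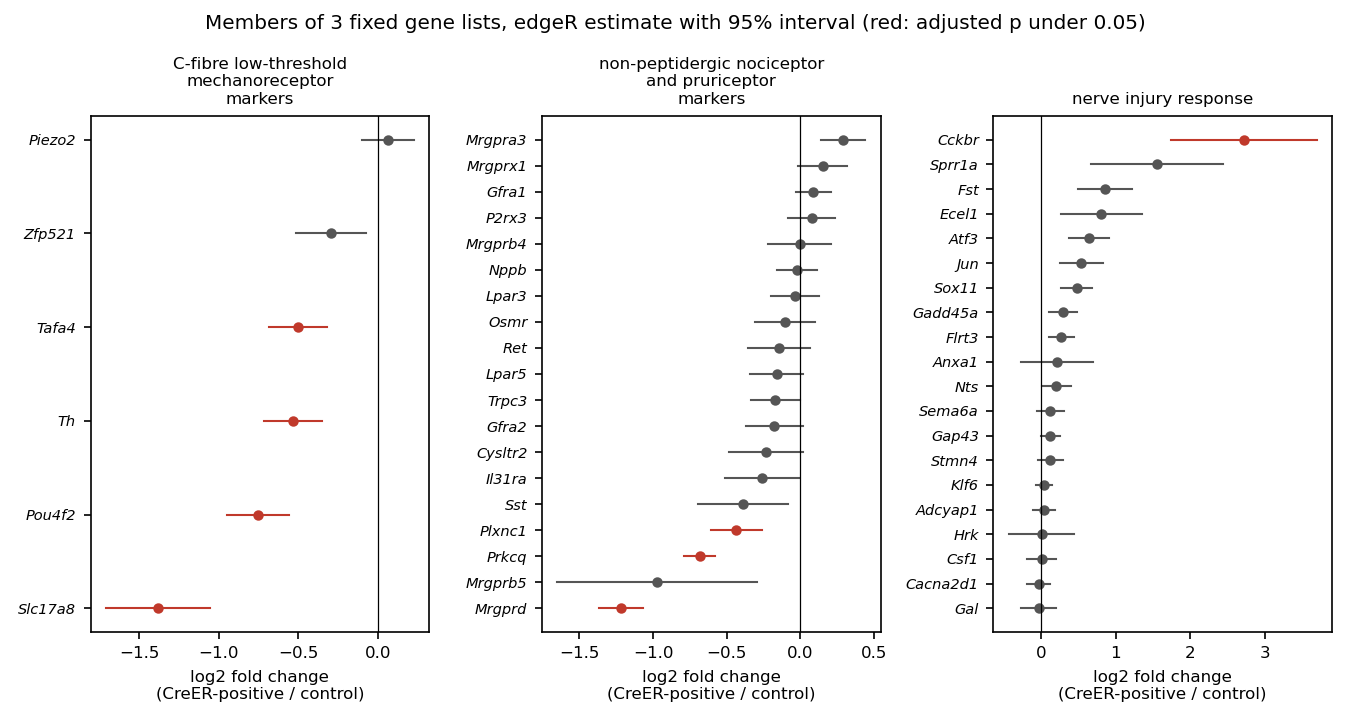
Log2 fold changes (horizontal axes, CreER-positive over control) with 95% intervals for the members of 3 lists, with red for edgeR adjusted p under 0.05. Slc17a8 (-1.38) and Mrgprd (-1.22) lie farthest below 0 in their lists, and Cckbr (2.71) farthest above 0 among injury genes.

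Among ion channels, individual genes moved in both directions. The nociceptor channel genes Scn10a (Nav1.8, 1081 to 869 CPM, -0.31) and Scn11a (Nav1.9, -0.23) did not pass, at edgeR adjusted p values of 0.156 and 0.234, and both passed by DESeq2 (0.000151 and 0.00970). Scn1a (-0.11), Scn3a (-0.09), Scn7a (-0.02) and Scn8a (0.04) were not called by edgeR or DESeq2. Of 27 potassium channel genes, Kcnn1, the calcium-activated channel SK1 (-0.59, edgeR adjusted p 0.00268), Kcnt1, a sodium-activated channel (-0.42), and Kcnd3, Kv4.3 (-0.44), fell, and Kcnc4, Kv3.4, rose (0.58). Of 20 sensory transduction genes, the irritant receptor gene Trpa1 rose (161 to 206 CPM, 0.36), as did Trpc5, and Trpc6 fell (-0.48). Of 17 calcium and HCN channel genes none was called by edgeR, 5 had an unadjusted p under 0.05 and DESeq2 called 2. The T-type calcium channel genes Cacna1h (-0.35) and Cacna1i (-0.88) had edgeR adjusted p values of 0.0530 and 0.0678. Syt7, a synaptotagmin gene of the release machinery, had -0.38 (0.0678 by edgeR and 3.65e-05 by DESeq2).

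As lists, calcium and HCN channels were called lower by camera (median -0.05, adjusted p 0.0358). That call was lost with an estimated correlation (0.737), by directional fry (0.551), without control replicate 2 (0.0557), without CreER-positive replicate 3 (0.350) and without both (0.555), while fry's mixed test called the list (0.0188). Sodium channel subunits (median -0.07, 0.0545) were called lower without control replicate 1 (0.0246) or CreER-positive replicate 1 (0.00918) or 2 (0.00456). Potassium channels had a median of -0.01, a mean of 0.00 with a positive sign and a camera direction down (0.433), and sensory transduction channels had 0.02 (0.563). Fry's mixed test called potassium channels (4.82e-05), sensory transduction channels (0.00265) and sodium channel subunits (0.00265). The neurotransmitter release machinery (0.02, 0.786) was called higher without CreER-positive replicate 3 (0.00343). Adjusted over the list alone, Scn10a and Scn11a were lower, 4 potassium channel genes higher and 5 lower, 3 transduction genes higher and 1 lower, 3 calcium channel genes lower and 1 release gene, Syt7, lower.

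Kcnn1 kept its call without any 1 library, while the other called channel genes named here lost theirs in at least 4 of the 6 such fits. Leaving out control replicate 1, 2 or 3 gave edgeR adjusted p values of 0.160, 0.0993 and 0.147 for Kcnc4. In the same order they were 0.180, 0.178 and 0.0669 for Kcnt1 and 0.219, 0.216 and 0.122 for Kcnd3. For Trpa1 they were 0.132, 0.143 and 0.109, and for Trpc6 0.120, 0.121 and 0.0539. Without CreER-positive replicate 1 the calls of Kcnc4 (0.0794), Kcnt1 (0.116) and Trpa1 (0.0785) ended, and without replicate 2 those of Kcnc4 (0.0736), Kcnt1 (0.0573), Kcnd3 (0.0991) and Trpc6 (0.0621). Cacna1i passed without CreER-positive replicate 1 (0.0147) or 3 (0.0234), and Scn10a (0.0308), Cacna1h (0.0164) and Syt7 (0.0308) without replicate 3.

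Opioid genes other than Penk showed no call by edgeR. The receptor genes Oprm1 (mu, 0.11), Oprd1 (delta, -0.19) and Oprk1 (kappa, -0.23) had edgeR adjusted p values of 0.683, 0.683 and 0.584. Oprl1, the nociceptin receptor gene, had 0.35 (0.207, and 0.0481 by DESeq2). Of 8 opioid peptide and receptor genes, Penk passed over all genes, and Penk and Oprl1 were higher adjusted over the list alone. The list's median was -0.04 while its mean was 0.19 and its camera direction up, with an adjusted p of 0.0585. It was called higher without CreER-positive replicate 1 (0.0261) or 3 (0.00807). With all libraries, fry's mixed test called the opioid list (0.00774).

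Stress, signalling and metabolic lists were not called by camera. For p53 targets (Phlda3 0.40, Ephx1 0.23) the median and adjusted p were 0.04 and 0.0579, for cholesterol synthesis (Dhcr7 0.19) 0.04 and 0.0585, and for heat shock (Hspa1b 0.24, Hspa5 0.11) 0.11 and 0.0585. For the circadian clock (Bhlhe41 -0.21, Clock -0.17) they were -0.08 and 0.225, for immediate early genes (Npas4 -0.66, Dusp1 0.21) -0.07 and 0.327, for the interferon response (Rsad2 -0.47, Ifi27l2a 0.12) -0.11 and 0.226, and for mitochondrial transcripts (ND2 0.20, ND1 0.22) 0.13 and 0.218. Of these lists, fry's mixed test called p53 targets alone (0.0209). No gene of these lists passed by edgeR over all genes, and the DESeq2 calls included 2 p53 targets and Rsad2. Adjusted over the list alone, 3 p53 targets were higher, Bhlhe41 was lower, and 0 heat shock, immediate early, interferon and mitochondrial genes were called. Without CreER-positive replicate 3, Rsad2 (0.0404) passed, cholesterol synthesis (0.00100) and heat shock (0.0288) were called higher and the interferon response lower (0.00343). Cholesterol synthesis was also called without control replicate 1 (0.0227), heat shock (0.0288) and the interferon response (0.000616) without control replicate 3, and p53 targets (0.0343) and mitochondrial transcripts (0.00537) without CreER-positive replicate 1.

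Libraries also differed in transcripts of cells other than sensory neurons. Control replicate 2 held muscle transcripts, with Myh4 at 10.8 CPM against at most 0.863 CPM elsewhere. Skeletal muscle markers (Myh4 -2.73, Mylpf -1.25) were called lower by camera (8 genes, median -2.03, 0.0367), not with an estimated correlation (0.737) or without CreER-positive replicate 1 (0.0735) or 3 (0.0688), and the direction turned up without control replicate 2 (0.0557). CreER-positive replicate 2 had 12.1 CPM of the oligodendrocyte gene Mobp against at most 2.77 CPM elsewhere. The 5 spinal cord markers (Mobp 2.10, Aqp4 0.20) were called higher (median 0.36, 0.0179), not with an estimated correlation (0.585) or without that library (0.118). CreER-positive replicate 3 had 4.87% mitochondrial counts against 3.08% to 3.57% elsewhere, and log2 means against the controls of 0.66 for macrophage, 0.53 for fibroblast and 0.76 for red blood cell markers. At 18 genes, among them Cdk8 and Lars2, CreER-positive replicates 1 and 3 had excess reads, 1.25% and 0.477% of counts against at most 0.121% in the other libraries. None of the 18 was called by edgeR, all 18 had an unadjusted p under 0.05, and DESeq2 called 2.

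Glial, immune, vascular and connective tissue lists were not called by camera with all libraries. The median and adjusted p were 0.06 and 0.130 for satellite glia (Kcnj10 0.23, Apoe 0.23) and 0.09 and 0.0545 for myelinating Schwann cells (Egr2 0.32, Prx 0.17). They were 0.20 and 0.218 for macrophages (Csf1r 0.29, C1qb 0.28), -0.20 and 0.293 for lymphocytes and neutrophils (Cd4 -0.51, S100a9 -0.23) and 0.13 and 0.218 for endothelial cells and pericytes, where the pericyte gene Rgs5 fell (-0.41) and Pdgfrb had 0.20. Fibroblast markers (Slc47a1 -0.54, Col1a2 0.27) had a median of 0.05 but a mean of -0.06, with the direction up (0.786). Red blood cell markers (Alas2 0.40, Hba-a2 0.47) had 0.40 and 0.193, and adipocyte markers (Pck1 -0.60, Cidec -1.04) -0.52 and 0.194. Rgs5 was the 1 gene called by edgeR in the marker lists of cells other than neurons, over all genes and adjusted over the list alone.

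Single libraries decided several of these marker results. Rgs5 (0.0293) lost its call without control replicate 1, 2 or 3 (0.160, 0.171 and 0.0539) or CreER-positive replicate 1 or 2 (0.0558 and 0.0778). Without CreER-positive replicate 1, satellite glia (0.00503), Schwann cell (0.000224), macrophage (0.00894), endothelial (0.000278) and fibroblast markers (0.0261) were called higher. Schwann cell markers were also called without control replicate 2 (0.000185), macrophage markers without control replicate 1 (0.0415) or CreER-positive replicate 2 (0.00532), and red blood cell markers without CreER-positive replicate 2 (0.00402). Without CreER-positive replicate 3, macrophage (0.0270) and fibroblast markers (0.0192) were called lower, as were adipocyte markers (0.0385), which were also called without control replicate 1 (0.0103).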

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

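Leaving out control replicate 2 and CreER-positive replicate 3 together and leaving out the 18 excess-read genes were chosen after seeing the data. None of the 160 genes changed sign in an alternative that tested it. That was nearly fixed in advance, since the CPM of the groups did not overlap for any of the 160. The 44 called genes with recomputed values gave 834 alternative values, of which 710 stayed called and 124 did not, and 21 of the 44 held in each of the 6 fits without 1 library. Other scalings, filters, limma-voom and robust or legacy settings called 157 to 194 genes. DESeq2 called 425 (156 higher, 269 lower), a test against a fold of 1.2 called 59 (7 higher, 52 lower), and 1 surrogate variable gave 784 (382 higher, 402 lower); the cause was not tested. Without both libraries the lower genes numbered 73. Without 1 library in turn the count ran from 60 to 568, with 6 to 333 higher and 54 to 235 lower genes. The count of called lists, 6, became 1 with an estimated correlation, 1 with directional fry (10 with its mixed test), 10 without both libraries and 11 without the excess-read genes, and ran from 5 to 14 without 1 library. The mechanoreceptor, non-peptidergic and injury lists were called in all 12 alternatives at the preset correlation. Skeletal muscle markers turned up without control replicate 2 (0.0557) and without both libraries (0.244), and ran from 1.71e-06 (without control replicate 1) to 0.0735 (without CreER-positive replicate 1) over single libraries. Without CreER-positive replicate 3, macrophage (0.0270) and fibroblast markers (0.0192) turned lower; without other libraries they reached 0.00532 (CreER-positive replicate 2) and 0.902 (control replicate 3), and 0.606 (control replicate 2). Scn9a was called in none of 19 alternatives (log2 fold change -0.09 to 0.00, adjusted p 0.789 or above).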

Other observations

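The genes named in this paragraph were chosen after their values were seen. Further signalling genes fell in CreER-positive ganglia by edgeR's quasi-likelihood test: Rasgrp1, a Ras activator gene (262 to 158 CPM, -0.73), Rgs8, a regulator of G protein signalling (78.3 to 37.1 CPM, -1.08), and Runx1, a transcription factor gene of non-peptidergic neurons (-0.43, edgeR adjusted p 0.0358). Potassium channel genes outside the fixed list fell too, Kcnf1 (-1.15) and Kcnj6 (-1.17), as did Abcc8 (-1.06), which encodes the sulphonylurea receptor of ATP-sensitive potassium channels. Adcy8, an adenylyl cyclase gene (0.63), and Sting1, an innate immune adaptor gene (0.70), rose. Rasgrp1, Rgs8, Kcnf1 and Abcc8 kept their calls without any 1 library. Runx1, Kcnj6, Adcy8 and Sting1 lost theirs without control replicate 1 (0.197, 0.166, 0.0547 and 0.104), 2 (0.140, 0.174, 0.0842 and 0.0882) or 3 (0.134, 0.0671, 0.0559 and 0.0879) or CreER-positive replicate 2 (0.1003, 0.102, 0.0564 and 0.0560). Wfdc2, Gm36090 and Gm14317, which fell, are neighbours on chromosome 2, between 164532189 and 164568510.

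Of the tests that follow, those on Mrgprd, the mechanoreceptor markers, Dpyd, Esr1 and a shared source of excess reads, and the counts over other splits of changed genes and of lists with an estimated correlation, were chosen after the results were seen. The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 160 genes and the highest of the others 3, so 1 of the 10 gave as many. All 10 splits called at least 6 lists by camera at the preset correlation, with 21 as the highest of the others. With an estimated correlation the real split called 1 list and each of the others 0, so a structure of the libraries other than the groups and a preset correlation too low for these lists were not separated. For the mechanoreceptor, non-peptidergic and injury lists the camera p was 2.77e-20, 1.58e-11 and 2.83e-12 in the real split, and the smallest of the others was 3.22e-05, 2.10e-05 and 0.000485. Other lists reached camera p values as small in splits other than the real one. The smallest were 4.39e-34 for the interferon response and 1.25e-22 for fibroblast markers, so such a p alone does not mark the groups.

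Mrgprd and mechanoreceptor markers were lower in all 3 CreER-positive mice. A loss of neurons that carry Mrgprd may be considered. The log2 ratio of Mrgprd to the mean of Lpar3 and P2rx3, which the same neurons carry, differed by -1.24 ± 0.0851 (SE). Lpar3 and P2rx3 were chosen after their values were seen, and other neurons carry them too. Prkcq (-0.68) and Plxnc1 (-0.43) of the same list were also called lower, and 4 of its 19 members had a positive estimate. A loss of these neurons and lower Mrgprd per cell therefore cannot be told apart. Fewer low-threshold mechanoreceptors cannot be told apart from lower levels per cell: Slc17a8, Pou4f2, Th and Tafa4 fell by unequal amounts (log2 ratio of Slc17a8 to Th -0.87 ± 0.154), but other cells may contribute to Th. An effect of the Scn9a deletion or of Cre activity stays open and was not tested, since both would go with the group.

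Dpyd and Esr1 had the highest rises of the called genes above 10 CPM. Reads of the CreER transgene may be counted at Esr1: the lowest CreER-positive library lay 28.9 CPM above the highest control, and without counts per exon this source cannot be told apart from Esr1 itself. For Dpyd, an effect of the transgene insertion on a stretch of chromosome 3 is a candidate explanation. Of 22 other tested genes within 2 Mb, edgeR called 0, and 6 had an unadjusted p under 0.05, against 2330 of all 22043 tested genes. DESeq2 called 2 of the 22 (1 higher, 1 lower), so an effect on the stretch and a change of Dpyd alone cannot be told apart. The insertion site is not given in the sources used here, and the deletion of Scn9a stays open as an untested explanation.

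CreER-positive replicates 1 and 3 had excess reads at 18 genes. For a single source, the excess in replicate 3 was read as a fraction of that in replicate 1. Over all 18 genes its highest over lowest ratio was 3.40, with 0.113 ± 0.0134 (counting SE) at Rmrp and 0.130 ± 0.00837 at Rn7sk. At the 15 genes with at least 10 CPM in the other libraries the fraction was 0.259 to 0.384, a ratio of 1.48. It differed there too beyond counting error (0.259 ± 0.00177 at Cdk8, 0.384 ± 0.00303 at Gm36876). The fraction was thus not constant in either set, and 1 source stays open for the 15 and for all 18. More non-polyadenylated RNA in these replicates stays open: Rn7sk, Rmrp and Rpph1 of the 18 lack a poly(A) tail, but genes of the pattern do not test it. For 19 replication-dependent histone genes, a set corrected after the result was seen, the median log2 ratio in replicate 1 was -0.0414, under the bound set before, but 13 of them lay under 1 CPM, so this excludes nothing. Library quality as the source of most genes called without replicate 2 is argued against by 141 of those 143 genes taken as a set. The 141 are the ones also tested with all libraries. Their shift in replicate 2 was a median 0.882 of that in replicates 1 and 3, against 0.0371 in counts simulated with replicate 2 at the control level. The 95% bootstrap interval, 0.784 to 0.971, came from resampling genes, so it measures spread over genes of 1 library and not over animals. Of the 141, 117 had the same sign, and 90 of the 143 are among the 160. The genes of the opposite sign and those outside the 160 were not examined separately, so library quality stays open for them.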
